A study of Mus musculus with 22 samples.

How the data were processed

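Per the submitters' processing notes, HISAT2 2.0.4, Trim Galore 0.4.3, Bismark 0.16.3 and methylKit 1.4.0 were used upstream with the builds mm10 and GRCm38, and the notes do not assign steps to tools. The deposited RNA values were read counts per gene symbol for 44792 genes, made by the authors with a counting tool and strand setting not given in the sources used here. The deposited RRBS values were, per the file headers, the percent of reads with a methylated cytosine (and of reads without) and the coverage at each CpG position of each strand, listed by the authors only where at least 10 reads lay. Per the labels, mice were C57BL/6, young and aged RNA libraries and all RRBS libraries were biological replicates, and NMDA and RPC RNA libraries were called replicates without more detail. Methods of dissociation, sort gates and the sex of the mice were not given in the sources used here.

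All 10 RNA libraries were fitted together in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood, after TMM scaling and the package's expression filter, which left 18931 genes. The fit had 6 residual degrees of freedom and a common biological coefficient of variation of 0.411. Genes were called at an adjusted p under 0.05. Each of NMDA, aged and RPC cells was compared with young Müller cells. Per-library levels are CPM, with n = 2 or 3. The comparisons, settings and alternatives were fixed before the data were examined, except those stated below to have been added, changed or chosen later. The gene end described below took the place of the planned transcription start site.

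Genes at 0 in 1 group have no finite fold, so their change was bounded with 3 counts over the pooled libraries of that group. Where the lower group had 1 to 3 counts, the ratio of pooled levels is given with a 95% interval, which leaves out variation between libraries. Gene positions came from the reference annotation, to which 32084 symbols could be matched, and a gene was marked as containing another if a second annotated gene lay within its span.

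The 23 fixed lists were Müller glia, gliosis and injury, retinal progenitor, neurogenic and early neuron, proliferation, pluripotency, DNA methylation machinery, Notch pathway, interferon and antigen presentation, senescence and inflammation, cholesterol synthesis, immediate early and dissociation, germline, imprinted, Hox and sex-linked genes, and markers of photoreceptors, inner retinal neurons, microglia and macrophages, vascular cells, pigment cells, lens and blood. Of the listed genes 2 were not in the table. Lists were tested with camera from limma 3.58.1 (correlation preset at 0.01, then estimated) and with fry on voom weights, adjusted over 22 lists per comparison. Members were also adjusted over their list alone.

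Genes named in the text followed a rule. For each RNA comparison it took the 5 highest and 5 lowest log2 changes among called genes with a mean of at least 8 CPM and no overlap between groups, leaving out predicted gene models and clone names, up to 3 members per list with the smallest adjusted p, and a fixed set that includes Rlbp1, Glul, Gfap, Lin28a, Lin28b and genes of DNA methylation and the nuclear factor I family. Results for genes withheld for evaluation were left out of the text. For methylation it took the 5 largest gains and losses among called ends without overlap, up to 3 called per list, and the fixed set.

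The 2 strands of a CpG were kept as separate positions, in the counts of CpGs and in the minimum per gene end. RRBS positions present in all 12 libraries numbered 759298, of which 743808 were autosomal and 718061 varied and were tested. Sex chromosomes were left out because the mice differed in sex, and 25747 constant positions carried no test. Methylated and unmethylated reads were modelled by group with a quasi-binomial model in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with overdispersion moderated across positions (prior 1.86 with 4.16 degrees of freedom, 8 residual) and an F test. A call needed an adjusted p under 0.05 and a pooled difference of at least 10 points. The annotation gave no strand, so the 2 ends of each protein-coding gene were taken and the end with more measured positions kept, within 1000 bp either side and with at least 5 positions. Of 20665 protein-coding genes 10460 had such an end, and 54 ends shared a window with another gene. These CpG-dense ends are not known to be transcription start sites. The mean level per library was compared by exact permutation of libraries.

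Alternatives for RNA were RLE and upper-quartile scaling, no filter, a filter of 5 CPM, a change of at least 2-fold, DESeq2 1.42.0, fits of the 2 groups or the Müller groups alone, the replicate number as a block, and each library left out in turn. For RRBS they were at least 20 reads, removal of coverage above the 99.9th percentile, sex chromosomes included, a plain logistic model, a minimum of 25 points at an adjusted p under 0.01, no minimum, the 2 groups alone, tiles of 1000 bp, windows of 500 bp, the block and each library left out. A minimum of 5 reads was planned and could not be run, because the files list only positions with at least 10. Added later were fits without genes that contain another gene, the other gene end, comparisons with aged in place of young cells, and the block with only 2 groups. The gene end was kept as first chosen under the 500 bp and 20-read alternatives only after a first run had let it change.

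Both tests were tried on simulated data built from the real libraries, the RNA one after the real comparisons had been run. With 18931 genes the RNA test recovered 22 of 100 genes changed 2-fold and 80 of 100 changed 8-fold, with 1 false call and 0 calls in the unchanged comparison. The simulated RNA libraries shared 1 mean profile and 1 spread per gene in all groups, whereas the real young libraries differed more than those of other groups. The number of false calls therefore need not hold for the real comparisons. The RRBS test recovered 0 of 100 positions changed by 20 points and 1 of 100 changed by 50 points when 200 positions changed. The number changed was then raised, with the test itself unaltered, and with 30000 changed it recovered 16.1% at 20 points and 87.0% at 50 points, with 174 false calls and 0 in the unchanged comparison. Recovery therefore depends on how many positions change. Figures were drawn with matplotlib 3.10.9, and files were read with the R package data.table (version 1.17.8).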

Results

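Gene expression and DNA methylation were measured in Müller glia, the main support cells of the retina, and in retinal progenitor cells (RPCs), the dividing cells from which the retina develops. Per the labels, Müller cells were sorted by flow cytometry from mice carrying a green fluorescent reporter driven by Rlbp1, a gene for a retinoid carrier of these cells. They came from young mice of 2 to 3 months, from young mice whose eyes had received NMDA, a glutamate receptor agonist that kills inner retinal neurons, 2 days before collection, and from aged mice of 1.5 years. RPCs came from embryonic day 12.5. RNA was sequenced from 2 young, 3 NMDA, 2 aged and 3 RPC libraries, and reduced representation bisulfite sequencing (RRBS), which reads methylation at cytosines of CpG-rich fragments, was done on 3 libraries of each of the 4 groups.

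RNA libraries held 15202738 and 10149390 counts in young cells, 15867733, 17824333 and 17968517 after NMDA, 36486072 and 33213893 in aged cells, and 14520423, 11067405 and 11442918 in RPCs. Expression is given as counts scaled by library size (CPM), mean ± SD, with n = 3 for NMDA and RPC and n = 2 for young and aged cells. Differences are log2 values ± standard error from edgeR with its adjusted p. RRBS libraries listed 1338829 to 2532174 CpG positions each, with the strands of a CpG as separate positions that were not merged, so that 1 CpG can count as 2, and the 759298 positions present in all 12 had a median coverage of 53 to 110 reads per library. Where every young library had 0 counts, folds were bounded with 3 counts over the pooled group, which is 0.118 CPM for young cells. Such bounds, and the 95% intervals of ratios below, cover counting error only and assume that no low counts were removed upstream. Libraries of 1 group differed by 5.71 to 83.1 times counting error (chi-square per degree of freedom over genes), so the true uncertainty is wider. The highest value was that of the 2 young libraries, the baseline of all 3 comparisons. Their log2 CPM correlated at Pearson r 0.884, against 0.962 to 0.994 for library pairs within the other groups. Young replicate 2 correlated with the aged libraries at 0.888 and 0.887, and young replicate 1 at 0.868 and 0.865. Genes with a count numbered 13913 and 14919 in the young libraries and 20920 to 23618 in the other libraries. In the young libraries 6.35% and 5.52% of detected genes had under 10 counts, against 14.3% to 29.5% in the other libraries. Among genes with 4 to 60 counts, 61.7% and 63.4% had an even count in the aged libraries and 50.5% to 53.9% in the others, for a reason the sources used here do not give.

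The first question was how young Müller cells respond to NMDA injury. Gfap, the intermediate filament gene that marks reactive glia, stood at 978 ± 167 CPM after NMDA and 30.9 ± 18.5 in young cells, a 33.7-fold rise (log2 5.07 ± 0.45, adjusted p = 7.6e-05; log2 5.91 without young replicate 1). Glul, the glutamine synthetase gene by which Müller cells clear glutamate, fell 7.17-fold, from 30171 ± 4938 to 3909 ± 1125 CPM (log2 -2.84 ± 0.26, adjusted p = 8.3e-05). Rlbp1, the gene of the sorting reporter, fell 3.26-fold, from 3780 ± 650 to 1078 ± 375 CPM (log2 -1.70 ± 0.36). Of 16 genes for making cholesterol 14 fell (camera adjusted p = 2.1e-08; adjusted p = 0.16 with an estimated correlation). Of 20 genes for cell division 11 rose, but that list did not pass (camera adjusted p = 0.095). No gene named below as changed in RNA overlapped between the libraries of its 2 groups.

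Of 26 gliosis and injury genes tested, 19 rose, 0 fell and 7 did not pass, and 21 rose when adjusted over the list alone (camera adjusted p = 1.7e-05; adjusted p = 0.27 with an estimated correlation). Stat3, a transcription factor of cytokine signalling, rose 3.49-fold from 114 ± 1.93 to 368 ± 16.6 CPM (log2 1.80 ± 0.11), and Osmr, the oncostatin M receptor gene, rose 4.90-fold (log2 2.29 ± 0.15). Cd44, a hyaluronan receptor gene, rose by log2 2.57 ± 0.21. Of 20 Müller glia genes, 7 fell, 1 rose and 12 did not pass, with the same 7 and 1 adjusted over the list alone (camera adjusted p = 2.8e-05; adjusted p = 0.60 with an estimated correlation). Besides Glul, Id3, a gene for an inhibitor of helix-loop-helix factors, fell (log2 -1.22 ± 0.10), whereas Acsl3, a fatty acid CoA ligase gene, rose (log2 2.68 ± 0.18). Of 16 cholesterol synthesis genes, 14 fell and 2 did not pass, and 14 fell when adjusted over the list alone (camera adjusted p = 2.1e-08; adjusted p = 0.16 with an estimated correlation). Insig1, a feedback regulator of sterol synthesis, fell 5.11-fold from 218 ± 84.6 to 39.7 ± 3.67 CPM (log2 -2.35 ± 0.22).

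Notch signalling maintains progenitors and the glial state of Müller cells, and of 17 Notch pathway genes 8 fell, 1 rose and 8 did not pass, the same 8 and 1 adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.40 with an estimated correlation). The target genes Nrarp (log2 -4.37 ± 0.38, from 152 ± 12.3 to 6.83 ± 3.33 CPM) and Hes5 (log2 -3.29 ± 0.34) fell, as did Notch2 (log2 -1.22 ± 0.15). Without genes that contain another annotated gene in their span, 4 of the Notch genes fell and 0 rose. Of 20 retinal progenitor genes, 8 fell, 5 rose and 7 did not pass, and 9 fell and 5 rose when adjusted over the list alone (camera adjusted p = 0.035, lower; adjusted p = 0.79 with an estimated correlation; camera adjusted p = 0.057 without NMDA replicate 2). The list's median log2 change was -0.02 as fitted and -0.33 with genes absent from 1 group at their bound, while its mean was 0.86. Fzd5, a Wnt receptor gene, fell (log2 -2.53 ± 0.22), and Lhx2, an eye-field transcription factor gene, rose (log2 5.63 ± 0.31), but stood at 1.28 CPM in RPCs and is one of 195 genes at least 8-fold higher in every NMDA and aged library than in every young and RPC library. Dpp4, a cell surface peptidase gene, was among the 5 most reduced genes (log2 -4.57 ± 0.38, 1.63 ± 0.510 against 41.6 ± 9.57 CPM).

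Of 20 proliferation genes, 11 rose and 9 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 0.095, not passed). Cdk1, the mitotic kinase gene, was higher by a ratio of 29.9 (95% interval 8.11 to 250) and Top2a, a topoisomerase gene of dividing cells, by 92.8 (31.6 to 451), both at low level (2.38 ± 0.913 and 11.1 ± 4.59 CPM). Ccnb1, a mitotic cyclin gene, was at least 10.1-fold higher. Of 17 DNA methylation genes, 6 rose, 3 fell and 8 did not pass, and 7 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.80). Uhrf1, which brings the maintenance methyltransferase to replicating DNA, was higher by a ratio of 103.1 (35.1 to 501), and Dnmt1, that methyltransferase, rose by log2 1.60 ± 0.11. Tet1, a 5-methylcytosine oxidase gene, fell (log2 -1.44 ± 0.18, adjusted p = 4.2e-04). Of 7 pluripotency genes, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.80), among them Myc, at least 210-fold higher, and Lin28a, an RNA-binding regulator of developmental timing, at least 11.3-fold higher at 1.33 ± 0.0711 CPM. That list's median was 3.65 as fitted and -0.33 with absent genes at their bound. The bound for Lin28a would not hold if low counts had been removed from the young libraries. Of 24 neurogenic and early neuron genes, 7 rose, 1 fell and 16 did not pass, and 2 rose when adjusted over the list alone (camera adjusted p = 0.88). The growth cone gene Gap43 rose by log2 3.19 ± 0.33, and Stmn2, a neuronal microtubule gene, was at least 261-fold higher. The neurogenic count was 4 up and 1 down without young replicate 2, 3 up without NMDA replicate 2 and 5 up without NMDA replicate 3.

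Of 22 interferon and antigen presentation genes, 12 rose and 10 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.79 with an estimated correlation). B2m, the light chain of class I antigen presentation, rose by log2 2.43 ± 0.36. Of 15 senescence and inflammation genes, 8 rose and 7 did not pass, and 9 rose when adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.60 with an estimated correlation). The stress cytokine gene Gdf15 was at least 52.0-fold, Igfbp3 at least 204-fold and the urokinase receptor gene Plaur at least 112-fold higher. Beside these gene groups, microglia and macrophage markers moved: 13 of 16 rose, also adjusted over the list alone (camera adjusted p = 0.22), and their summed level was 498, 4898 and 1010 CPM in the 3 NMDA libraries against 30.5 and 157 in young cells. Summed interferon genes (1608, 2666 and 2026 CPM) and senescence genes (336, 671 and 270 CPM) were also highest in NMDA replicate 2. In young cells these sums were 998 and 732 CPM, and 201 and 162 CPM. Whether microglia contributed to both rises was not tested. Without NMDA replicate 2, 8 microglia genes rose, 1 fell and the camera adjusted p was 0.013 (adjusted p = 0.73 with an estimated correlation). Trem2, a microglial receptor gene, was at least 260-fold higher, and the lysozyme gene Lyz2 stood at 824 ± 980 CPM against 1.77 ± 2.51 (log2 9.17 ± 1.65; from 7.50 without NMDA replicate 2 to 16.99 without young replicate 2).

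Of 11 vascular genes, 6 rose and 1, the pericyte receptor gene Pdgfrb (log2 -1.55 ± 0.18), fell, also adjusted over the list alone (camera adjusted p = 0.22). Of 8 pigment cell genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.43), and of 9 lens genes 1 rose and 0 passed when adjusted over the list alone (camera adjusted p = 0.43). Summed lens genes reached 789 CPM in NMDA replicate 2 against 39.8 and 52.5 in the other NMDA libraries. Of 20 photoreceptor genes 4 rose, 2 when adjusted over the list alone (camera adjusted p = 0.65), with 8 up without young replicate 1 and 2 up without NMDA replicate 2 or NMDA replicate 3. Upper-quartile scaling gave 2 photoreceptor genes up and 2 down. Of 20 inner retinal neuron genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.43), with 10 up and 1 down without young replicate 1 and 8 up and 3 down without young replicate 2. None of 10 blood genes passed with edgeR (2 at an unadjusted p under 0.05; DESeq2 called 2 up and 2 down; camera adjusted p = 0.32), and 2 fell without young replicate 2.

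Immediate early and dissociation genes, which tissue handling induces within minutes, fell for 7 of 14 genes, also adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.60 with an estimated correlation). Hspa1b, a heat shock gene, fell by 1.09 ± 0.26 and the early response gene Ier2 by 1.75 ± 0.38 on the log2 scale, the latter to -0.81 without young replicate 1. The count was 3 down and 1 up without young replicate 1, 3 down without NMDA replicate 1 and 4 down without NMDA replicate 3. The summed level was 11019 and 4705 CPM in the 2 young libraries and 3566, 4081 and 4087 after NMDA. Of 19 imprinted genes 8 fell and 4 rose, 8 and 6 when adjusted over the list alone (camera adjusted p = 0.13), with Peg10 lower (log2 -2.70 ± 0.32; -2.07 without young replicate 1). Of 4 germline genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.44): the germ cell helicase gene Ddx4, at least 14.3-fold. A second germline gene passed without young replicate 1 or NMDA replicate 2, and 1 rose and 1 fell without young replicate 2. No Hox gene was expressed enough to be tested. No sex-linked gene of 5 passed with edgeR (0 at an unadjusted p under 0.05, 0 with DESeq2; camera adjusted p = 0.43), with 1 up without young replicate 1 and 4 down without NMDA replicate 1. Xist, expressed in female cells, was high in young replicate 1 (2723 CPM) and in NMDA replicates 2 and 3, and low in both aged libraries (0.685 and 0.0301 CPM), so the groups differed in sex.

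In all, 8497 of 18931 genes tested differed between NMDA and young cells, 5795 higher and 2702 lower. These were 7409 and 4295 without young replicate 1, 8473 and 4143 without young replicate 2, and 5110 to 5209 and 2082 to 2236 without 1 NMDA library. Upper-quartile scaling, which moved the median log2 change of all genes from 0.26 to 0.04, gave 5094 higher and 3825 lower. The filter of 5 CPM gave 3626 higher and 2768 lower of 14078 genes, so the excess of higher genes lay largely at low levels. Acsl3, Cd44, Lhx2, Gap43, Top2a, Dnmt1 and Notch2 contain another annotated gene in their span, and such genes were called higher in 47.7% of cases against 26.5% of other genes. A fit with the 2 groups alone called 4895 genes. For photoreceptor genes the median and mean were positive and the list test pointed down, and for imprinted genes the median and the test were negative and the mean positive.

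**Figure D1:**
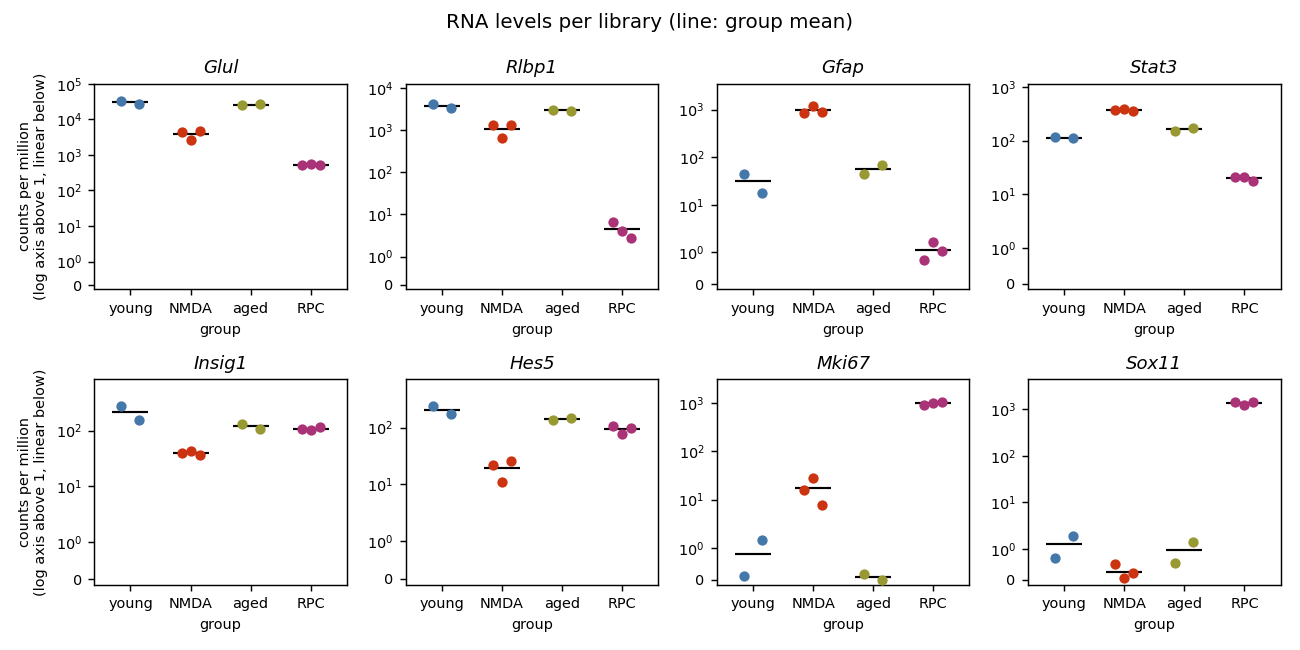
Expression of 8 genes per RNA library in CPM, on an axis that is logarithmic above a linear range near 0, with each point 1 library grouped as young, NMDA, aged and RPC. Gfap lies near 978 CPM after NMDA and near 30.9 in young cells, while Glul falls from 30171 in young cells to 3909 after NMDA.

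The second question was how Müller cells differ with age. Glul and Rlbp1 did not pass: Glul stood at 25826 ± 852 CPM in aged and 30171 ± 4938 in young cells (log2 -0.04 ± 0.28, adjusted p = 0.97), and Rlbp1 at 2944 ± 210 and 3780 ± 650 (log2 -0.17 ± 0.40, adjusted p = 0.81). Gfap stood at 57.3 ± 17.4 and 30.9 ± 18.5 CPM and missed the threshold (log2 1.06 ± 0.40, adjusted p = 0.085), but passed without young replicate 1 (log2 1.90). A small part of the injury set was higher, with Stat3 at 1.63-fold (log2 0.70 ± 0.12, adjusted p = 0.0029) and Osmr at 1.74-fold (log2 0.80 ± 0.15, adjusted p = 0.0054).

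Of 26 gliosis and injury genes, 9 rose and 17 did not pass, the same 9 adjusted over the list alone (camera adjusted p = 0.37). The metalloreductase gene Steap4 was at least 59.3-fold higher at 7.02 ± 1.91 CPM. Of 20 Müller glia genes 1 rose (Acsl3, log2 3.37 ± 0.19) and 2 fell, 1 and 1 when adjusted over the list alone (camera adjusted p = 0.45). Id3 fell by 0.76 ± 0.11 on the log2 scale. Of 20 retinal progenitor genes 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.96), and 3 rose without aged replicate 2. Six6, an eye-field transcription factor gene, rose by log2 1.23 ± 0.16 and Lhx2 by 6.56 ± 0.33. Of 16 cholesterol synthesis genes 3 fell and 13 did not pass, 3 when adjusted over the list alone (camera adjusted p = 0.0065; adjusted p = 0.89 with an estimated correlation; camera adjusted p = 0.16 without genes that contain another gene). The cholesterol count was 5 down without young replicate 1, 3 up and 4 down without young replicate 2, and 1 down without either aged library.

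Of 20 proliferation genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.094). Mcm2, a subunit of the replication helicase, fell by 1.10 ± 0.19 on the log2 scale. That count was 2 up and 3 down without young replicate 1 and 2 up and 4 down without young replicate 2. Of 17 DNA methylation genes 4 rose, also adjusted over the list alone (camera adjusted p = 0.67). Dnmt1 rose by log2 1.03 ± 0.12 and Uhrf1 was higher by a ratio of 7.64 (95% interval 2.50 to 38.0). The methylation count was 7 up and 1 down without young replicate 1 and 5 up and 3 down without young replicate 2. Of 7 pluripotency genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.60), with Lin28a at least 7.0-fold higher at 0.829 ± 0.107 CPM. At so low a level this bound would not hold if low counts had been removed from the young libraries. Of 24 neurogenic genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.37), and 1 rose without aged replicate 2. Of 17 Notch genes 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.64), with 5 up and 2 down without young replicate 2. Of 22 interferon genes 4 rose, 3 when adjusted over the list alone (camera adjusted p = 0.96), and 2 rose without aged replicate 1. Of 15 senescence and inflammation genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.64), with Gdf15 at least 4.93-fold higher. That count was 4 up and 1 down without young replicate 2 and 1 up without aged replicate 1.

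Immediate early genes fell for 2 of 14, also adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.89 with an estimated correlation), with 11 down without young replicate 2 and 1 down without either aged library. The orphan receptor gene Nr4a1 fell by 1.99 ± 0.39 (log2 -1.22 without young replicate 1) and missed the threshold without aged replicate 2 (adjusted p = 0.059). Of 20 photoreceptor genes 3 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0058, lower; adjusted p = 0.89 with an estimated correlation). That count was 3 up without young replicate 1, 2 up and 11 down without young replicate 2, 1 up and 1 down without aged replicate 1, and 2 up without aged replicate 2. Summed photoreceptor genes were 15731 and 10658 CPM in young and 9695 and 6422 in aged libraries. Of 16 microglia genes 3 rose, 1 when adjusted over the list alone (camera adjusted p = 0.64), with Trem2 at least 28.5-fold higher. The microglia count was 9 up without young replicate 2 and 1 up without any other single library. Of 11 vascular genes 6 rose, 7 when adjusted over the list alone (camera adjusted p = 0.094), among them the tight junction gene Cldn5, at least 9.61-fold. Of 20 inner retinal neuron genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.64), with 11 up without young replicate 1 and 9 up and 2 down without young replicate 2.

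Of 8 pigment cell genes 4 rose, also adjusted over the list alone (camera adjusted p = 0.41), of 4 germline genes 2, also adjusted over the list alone (camera adjusted p = 0.45), with Ddx4 at least 11.96-fold higher. The germline count was 1 without young replicate 2 or aged replicate 2. Of 19 imprinted genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.73), with Peg3 at log2 2.63 ± 0.14 and Snrpn at -9.69 ± 0.53 (-12.88 without aged replicate 1). The imprinted count was 6 up and 4 down without young replicate 2, and 0 passed without genes that contain another gene. With edgeR none of 9 lens genes passed (1 at an unadjusted p under 0.05, 1 with DESeq2; camera adjusted p = 0.91), and 1 rose without young replicate 1 or aged replicate 2. None of 10 blood genes passed (2 at an unadjusted p under 0.05; 1 up and 3 down with DESeq2; camera adjusted p = 0.19), and 2 fell without young replicate 2. None of 5 sex-linked genes passed (1 at an unadjusted p under 0.05, 1 with DESeq2; camera adjusted p = 0.71), and 1 fell without young replicate 2. No Hox gene could be tested.

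In all, 5105 genes differed between aged and young cells, 3997 higher and 1108 lower. Upper-quartile scaling, which moved the median of all genes from 0.13 to 0, gave 3527 and 1848. The filter of 5 CPM gave 2276 higher and 1145 lower of 14078 genes. The largest rises by the fixed rule, such as Trpm3, Gnas and Rnf213, and also Acsl3, Lhx2, Dnmt1, Peg3 and Snrpn, belonged to genes that contain another gene, which were called higher in 40.0% of cases against 15.5% of others. Lhx2, Trpm3, Gnas and Rnf213 are among the 195 genes at least 8-fold higher in every NMDA and aged library than in every young and RPC library. The largest falls included Rbm4, at least 1345-fold lower. The count was 341 with the 2 groups alone in the fit, 3291 with the Müller groups alone and 2605 without genes that contain another gene. Müller, Notch and lens lists had a positive median and mean but a list test that pointed down, neurogenic and proliferation lists had a positive mean against a negative median and test, imprinted genes a positive median against a negative mean and test, and sex-linked genes a negative mean against a positive median and test. The count of genes was 8295 without young replicate 1 (5620 higher, 2675 lower), 10469 without young replicate 2 (7126 and 3343), 3334 without aged replicate 1 (2951 and 383) and 3334 without aged replicate 2 (2978 and 356).

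The third question was how Müller cells differ from the progenitors they arise from. In RPCs all 20 Müller glia genes were lower, also adjusted over the list alone, and all 20 proliferation genes were higher, also adjusted over the list alone (camera adjusted p = 1.7e-14 and 5.3e-08; adjusted p = 0.35 for each with an estimated correlation). Rlbp1 stood at 4.48 ± 2.07 CPM in RPCs and 3780 ± 650 in young cells (log2 -9.82 ± 0.50, adjusted p = 7.7e-07), and Kcnj10, the potassium channel gene of Müller cells, at 0.418 ± 0.134 and 1030 ± 30.1 (log2 -11.41 ± 0.27). Sfrp2, a secreted Wnt modulator gene of the early retina, reached 2166 ± 59.4 CPM against 0.164 ± 0.0463 (log2 13.55 ± 0.23). Fgf15, a growth factor gene of progenitors, reached 598 ± 56.6 CPM, at least 5055-fold higher than in young cells, where it was listed at 0.

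Glul was lower (log2 -5.96 ± 0.29), and Slc1a3, the glutamate transporter gene, by a log2 change of -5.50 ± 0.14. Of the division genes, the ribonucleotide reductase gene Rrm2 was at least 2855-fold, Ccnb1 at least 1949-fold and the checkpoint kinase gene Bub1 at least 1557-fold higher, and Cdk1 was higher by a ratio of 2062 (95% interval 571 to 17034). The replication helicase gene Mcm5 rose by log2 4.93 ± 0.26 and Tyms, for thymidylate synthase, by 3.08 ± 0.14. Of 24 neurogenic and early neuron genes 22 rose, 23 when adjusted over the list alone (camera adjusted p = 4.7e-06; adjusted p = 0.35 with an estimated correlation). The proneural gene Atoh7, needed for ganglion cells, was higher by a ratio of 5515 (1527 to 45546), Foxn4 by 2547 (705 to 21034), and Sox11 by log2 10.03 ± 0.57 (9.44 without young replicate 1, 10.76 without young replicate 2). Of 20 retinal progenitor genes 9 rose, 5 fell and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.57), and 5 rose and 4 fell without genes that contain another gene. Of 7 pluripotency genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.51). Lin28a was at least 212-fold higher, whereas the transcription factor genes Esrrb (log2 -7.89 ± 0.47) and Klf4 (log2 -4.17 ± 0.41) fell.

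Of 17 DNA methylation genes 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.51). Uhrf1 was higher by a ratio of 4056 (1388 to 19668), Dnmt1 rose by log2 2.03 ± 0.12, the de novo methyltransferase gene Dnmt3b by 4.98 ± 1.13 (3.92 without young replicate 1, 13.99 without young replicate 2) and Tdg, the glycosylase that removes oxidised methylcytosine, by 2.72 ± 0.16. Of 17 Notch genes 6 rose and 7 fell, 7 and 7 when adjusted over the list alone (camera adjusted p = 0.50), with Lfng, a modifier of Notch, lower (log2 -2.71 ± 0.16) and a positive mean against a negative median and list test. Of 26 gliosis genes 17 fell and 5 rose, 18 and 5 when adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.35 with an estimated correlation). Stat3 fell (log2 -2.65 ± 0.11), and Osmr was lower by a ratio of 1949 (539 to 16098). Of 22 interferon genes 20 fell, 21 when adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.35 with an estimated correlation), with Ifit3 at log2 -7.84 ± 0.32. Of 15 senescence and inflammation genes 3 rose and 3 fell, 3 and 2 when adjusted over the list alone (camera adjusted p = 0.65), with 1 up and 5 down without young replicate 1. The growth factor binding gene Igfbp5 rose by log2 2.56 ± 0.43 (3.34 without young replicate 1). Of 16 cholesterol synthesis genes 6 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 1.0). The synthase gene Hmgcs1 rose by log2 1.74 ± 0.18 and Sc5d fell by 1.21 ± 0.13.

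All 20 photoreceptor genes and all 14 immediate early genes were lower in RPCs, also adjusted over the list alone (camera adjusted p = 2.3e-10 and 2.8e-07; adjusted p = 0.37 and 0.35 with an estimated correlation). The disc rim gene Prph2 was lower by a log2 change of -13.50 ± 0.48 and Fos by -11.69 ± 0.50 (-10.91 without young replicate 1). Summed photoreceptor genes were 14.3, 12.1 and 12.1 CPM in RPCs and 15731 and 10658 in young cells. Blood genes were higher for 9 of 10, also adjusted over the list alone (camera adjusted p = 0.092), with summed levels of 11027, 3381 and 1737 CPM in RPCs and at most 12.4 in any other library. The embryonic globin gene Hba-x was higher by a ratio of 5373 (1838 to 26056). Of 20 inner retinal neuron genes 8 rose and 8 fell, 8 and 9 when adjusted over the list alone (camera adjusted p = 0.51), with the ganglion cell factor gene Pou4f1 at least 174-fold higher. Of 16 microglia genes 3 rose, 1 when adjusted over the list alone (camera adjusted p = 0.92), with 1 up without young replicate 1 and 7 up without young replicate 2. Of 11 vascular genes 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.68), with Pdgfrb at log2 -5.46 ± 0.20. Of 8 pigment cell genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.19). Of 9 lens genes 1 rose, 0 when adjusted over the list alone (camera adjusted p = 1.0), with 1 up and 1 down without RPC replicate 2.

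Of 19 imprinted genes 11 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.50), with Zrsr1 lower (log2 -3.50 ± 0.17). Of 4 germline genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.26), with Dazl at least 13.0-fold and Tdrd1 at least 21.6-fold higher. None of 5 sex-linked genes passed with edgeR (0 at an unadjusted p under 0.05, 0 with DESeq2; camera adjusted p = 0.68), and 1 rose without young replicate 1. The nuclear factor I genes Nfix (log2 -7.93 ± 0.29), Nfia (log2 -5.69 ± 0.22) and Nfib (log2 -2.59 ± 0.15) fell. In all, 11508 genes differed, 6795 higher and 4713 lower in RPCs. The filter of 5 CPM gave 4646 higher and 4337 lower of 14078 genes. Nfia, Nfib, Nfix and Dnmt1 contain another gene, and without such genes 7652 of 12507 differed.

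**Figure D2:**
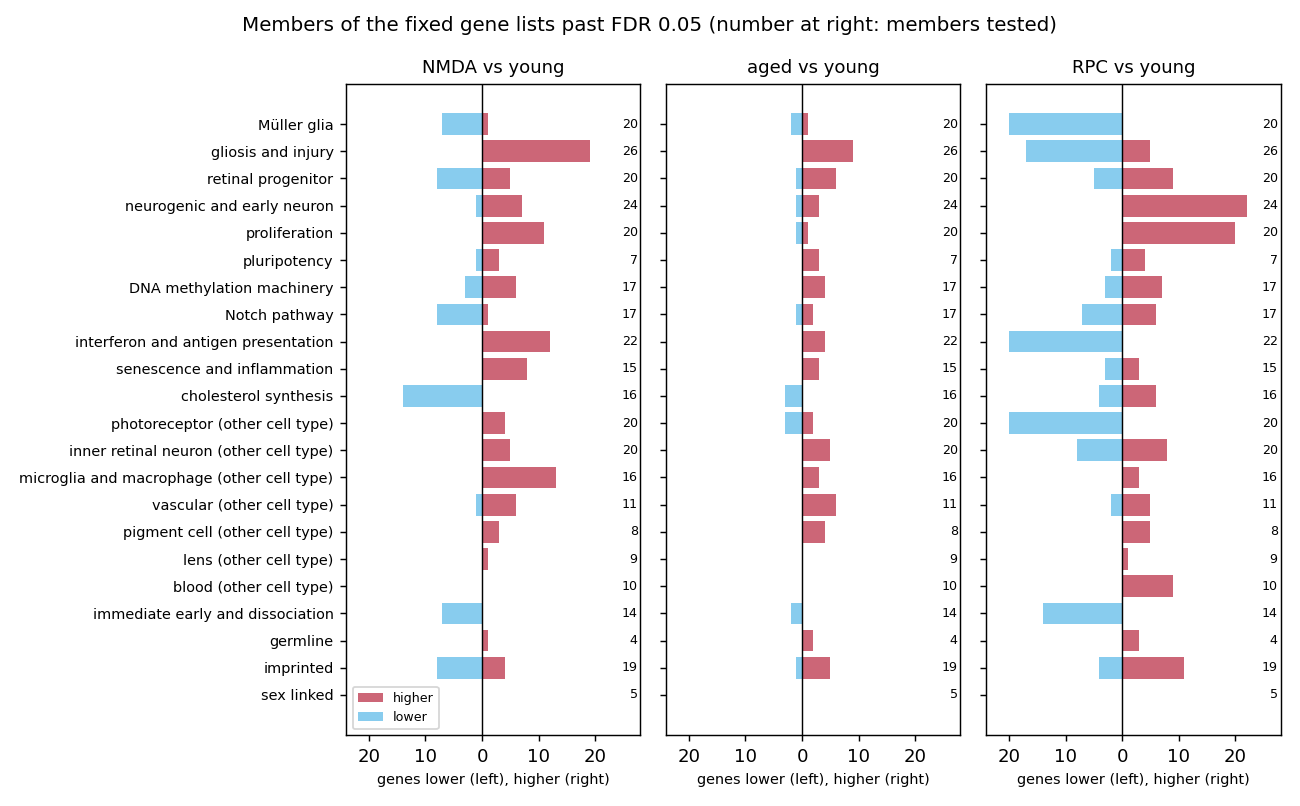
Number of genes of each fixed list called higher (right) or lower (left) than in young cells at an adjusted p under 0.05, for NMDA, aged and RPC cells, with the number tested at the right. Gliosis genes rose for 19 of 26 after NMDA, cholesterol synthesis genes fell for 14 of 16, and all 20 Müller glia genes fell in RPCs.

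Methylation after NMDA was compared with that of young cells to see whether injury alters it. Near CpG-dense ends of genes, gains outnumbered losses 184 to 21. The largest gain was at Cav3, for a muscle caveolin, from 21.0 ± 0.588% to 79.3 ± 17.3% (SD, n = 3 each; mm10 chromosome 6, 112458505 to 112460505, 5 positions, at least 72 reads per library). At Pkd2, for a ciliary cation channel, methylation rose from 9.29 ± 0.960% to 47.3 ± 10.4% (chromosome 5, 104452982 to 104454982, 9 positions, at least 547 reads; adjusted p = 5.6e-05). At Fsbp methylation fell from 67.5 ± 6.17% to 36.0 ± 6.22% (chromosome 4, 11578662 to 11580662, 7 positions, at least 261 reads).

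The measured ends of Cachd1 (pooled difference 38.7 points), Tmem267 (35.6 points, but 1.45 points within 500 bp, where the call was lost) and Eps8l3 (35.3 points) also gained. Spx and Pdc, the photoreceptor gene phosducin, lost methylation (differences of -26.8 and -19.7 points). Of fixed lists, 6 of 11 measured imprinted gene ends gained and 0 lost, with Plagl1 at 21.5 points and Nnat at 20.9 points, the latter not called without NMDA replicate 1 (adjusted p = 0.055). Of the 6 ends, those of Sgce and Peg10 shared 1 window and so 1 value. Over 6 imprinted ends with a mean of at least 15%, which count this window for both genes, young libraries stood at 10.4, 37.7 and 28.1% and NMDA libraries at 47.8, 38.6 and 41.5%, so young replicate 1 lay apart and young replicate 2 near NMDA replicate 2. Igf2r gained 11.2 points and fell under the minimum of 10 points without NMDA replicate 2 (9.72) or NMDA replicate 3 (9.46). Clu, a chaperone gene of the Müller list, gained 10.8 points, and 9.58 without young replicate 1 or 8.95 without NMDA replicate 3. The pluripotency gene Tdgf1 gained 12.2 points and Pdgfrb 13.2 points, the latter not called with at least 20 reads per position (2.14 points). None of 16 Hox and none of 5 germline gene ends was called. The Glul end stood at 0.622 ± 0.0873% after NMDA and 3.69 ± 0.706% in young cells, which is below the minimum difference.

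Over single CpGs, 14289 gained and 7304 lost methylation, of 718061 tested, with median differences of 26.8 and -14.8 points among those called. With no minimum difference the balance turned, to 15357 gains and 24052 losses, and without young replicate 3 it was 9157 gains and 9503 losses. Of the 512367 CpGs under 20% in young cells, 10884 gained and 4466 lost. The mean level over 743808 autosomal CpGs was 23.9 ± 0.358% after NMDA and 23.8 ± 0.748% in young cells (exact permutation p = 0.8, two-sided; 3 against 3 cannot give less than 0.1). With reads pooled over CpGs it was 27.8 ± 4.17% and 14.5 ± 3.59% (exact permutation p = 0.1), and with at least 20 reads the difference was -0.202 points (exact permutation p = 0.6). With 1 library left out it ran from -0.156 (without young replicate 1) to 0.583 (without young replicate 2), so its sign was not fixed. Of the 205 gene ends called, 177 had no overlap between the 2 groups' libraries (10% by chance), but calls and overlap rest on the same values, so this is no separate support. With the quasi-binomial test 8214 of 10460 gene ends had an unadjusted p under 0.05, so the adjusted p was little stricter than the unadjusted one. Median differences were negative in every measured list but germline and imprinted genes. The 21593 CpGs called became 1 without young replicate 1, 6950 without young replicate 2, and 5339, 1306 and 1822 without NMDA replicates 1, 2 and 3. A fit with the 2 groups alone called 0 CpGs with the quasi-binomial test (145710 at an unadjusted p under 0.05, and 94521 with a plain logistic model of all groups) and 197 gene ends.

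The same measurements were compared between aged and young cells. Single CpGs mainly lost methylation, 25548 against 3161 that gained, with most losses at CpGs under 20% in young cells. Gene ends changed both ways, 37 up and 38 down. Methylation at Dbndd1 rose from 38.4 ± 17.1% to 72.2 ± 5.12% (SD, n = 3 each; chromosome 8, 123517277 to 123519277, 20 positions, at least 869 reads) and at Rgs7, a regulator of G protein signalling in neurons, from 10.7 ± 6.56% to 33.5 ± 7.98% (chromosome 1, 175491862 to 175493862, 20 positions, at least 488 reads). Fsbp fell from 67.5 ± 6.17% to 47.2 ± 2.78% (adjusted p = 9.2e-04).

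Osgin1 gained 41.3 points and Thoc1 34.5 points, but within 500 bp these differences were -4.84 and -3.42, and Thoc1 was not called without young replicate 1 (adjusted p = 0.054). Cachd1 gained 27.7 points. Sec31b showed a difference of -24.2 points, Bnipl of -19.7 and Unc45a of -19.3, all 3 not called within 500 bp (-1.71, 4.30 and -1.96). Of the fixed lists, Pdc (-12.2 points) lost and Pdgfrb (12.3 points) gained, Pdgfrb not with at least 20 reads (-2.14). The germline gene Dazl gained 29.2 points, but its call was lost without young replicate 1, aged replicate 1 or aged replicate 2 (adjusted p = 0.20, 0.16 and 0.090), and the difference was -0.451 with at least 20 reads. None of 16 Hox gene ends was called.

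Of the CpGs under 20% in young cells, 18502 lost and 1342 gained methylation. Positions at 5 to 20% made up 16.3 to 20.3% of young libraries and 7.10 to 8.09% of aged libraries. Part of the losses at low levels may thus come from the young libraries rather than from age. Both NMDA and aged cells were lower than young cells at 5828 CpGs (260 by chance, with the young libraries shared). The median difference among called losses was -14.2 points. Tiles of 1000 bp showed no excess of losses, with 393 gains and 358 losses. The mean level was 22.1 ± 0.353% in aged and 23.8 ± 0.748% in young cells (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). With reads pooled over CpGs the sign turned, to 16.5 ± 3.06% in aged and 14.5 ± 3.59% in young cells (exact permutation p = 0.5). With 1 library left out the difference ran from -2.04 (without young replicate 1) to -1.30 points (without young replicate 2). Of the 75 gene ends called, 68 had no overlap between libraries (10% by chance), which rests on the same values as the calls. With the quasi-binomial test 8759 of 10460 gene ends had an unadjusted p under 0.05. The 28709 CpGs called became 10310, 16161 and 11954 without aged replicates 1, 2 and 3. With the 2 groups alone in the fit the count was 0 with the quasi-binomial test (172540 at an unadjusted p under 0.05, and 77149 with a plain logistic model of all groups), and 77 gene ends.

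RPCs were compared with young cells in the same way. At Vps37b, for a subunit of an endosomal sorting complex, the level was 96.2 ± 0.847% in RPCs and 10.8 ± 1.78% in young cells (SD, n = 3 each; chromosome 5, 124003641 to 124005641, 12 positions, at least 484 reads; adjusted p = 1.1e-09). Pkd2, which gained after NMDA, stood at 94.9 ± 1.10% in RPCs. At the Rlbp1 end the level was 78.0 ± 2.98% in RPCs and 55.9 ± 5.37% in young cells (chromosome 7, 79391250 to 79393250, 6 positions, at least 91 reads; adjusted p = 0.0085, and 0.062 without young replicate 1). At Sv2c, a synaptic vesicle gene, it was 8.77 ± 4.57% in RPCs and 54.3 ± 5.32% in young cells (chromosome 13, 95958443 to 95960443, 10 positions, at least 261 reads).

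Vwa7, Serpinf2 and Rarres2 were higher by 84.4, 81.2 and 78.9 points in RPCs, and Lrtm1, Mrps23 and Lypd2 differed by -41.8, -41.6 and -41.1 points. Of the Müller glia list 3 ends were higher in RPCs: Rlbp1, Clu (15.6 points) and Kcnj10 (13.8 points; 8.60 within 500 bp, under the minimum). The pluripotency gene Tdgf1 was at 2.90 ± 0.478% in RPCs and 30.0 ± 1.81% in young cells, the endothelial adhesion gene Esam differed by -13.2 points and the lens crystallin gene Crygd by 21.4 points. Of 11 imprinted gene ends 4 were higher, among them Plagl1 (22.2 points), Nnat (21.6 points) and Zrsr1 (13.9 points; 9.10 without young replicate 1). Over the 6 imprinted ends above RPC libraries stood at 49.9, 39.1 and 43.5%, with RPC replicate 2 near young replicate 2. Of 5 germline gene ends Dazl was higher by 31.2 points, but was not called without young replicate 1, RPC replicate 2 or RPC replicate 3 (adjusted p = 0.13, 0.062 and 0.11) and differed by -0.195 points with at least 20 reads. None of 16 Hox gene ends was called.

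In all, 269 gene ends were higher and 116 lower in RPCs, of 10460 tested. Of the 385 called, 355 had no overlap between libraries (10% by chance), which rests on the same values as the calls. With the quasi-binomial test 7477 ends had an unadjusted p under 0.05. Of single CpGs 34352 were higher and 19253 lower, with median differences of 45.2 and -20.1 points among those called. With no minimum difference 36677 were higher and 54100 lower. The mean level was 24.6 ± 0.412% in RPCs and 23.8 ± 0.748% in young cells (exact permutation p = 0.2, two-sided; the smallest possible is 0.1). With reads pooled over CpGs it was 25.9 ± 2.36% and 14.5 ± 3.59% (exact permutation p = 0.1), and with at least 20 reads the difference was 0.325 points (exact permutation p = 0.5). With 1 library left out it ran from 0.455 (without young replicate 1) to 1.19 points (without young replicate 2). With the 2 groups alone in the fit 25319 CpGs were called.

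**Figure D3:**
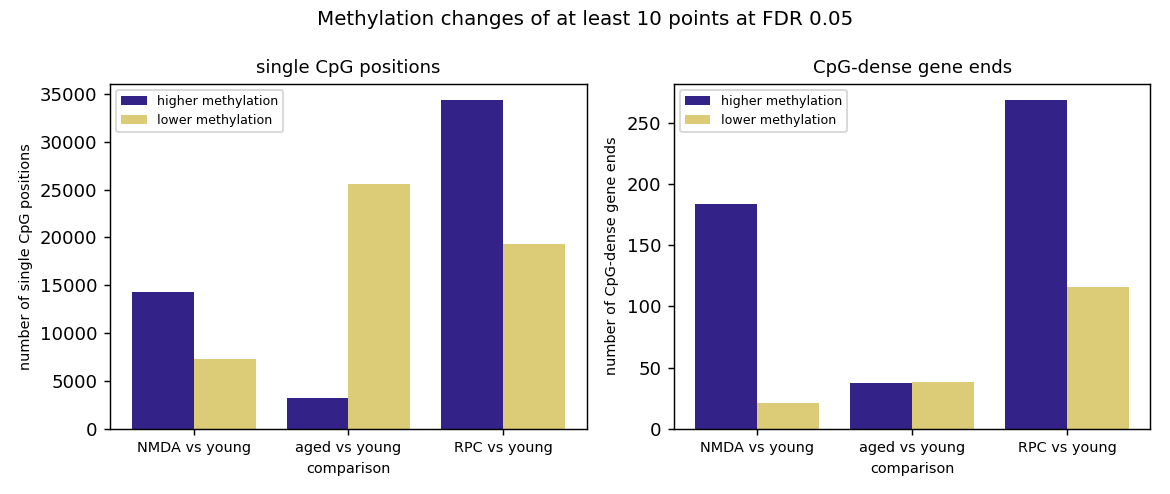
Number of CpGs and of gene ends with higher (gain) or lower (loss) methylation than in young cells, for NMDA, aged and RPC cells, from RRBS with 3 libraries per group. At a minimum of 10 points gains outnumber losses after NMDA (14289 and 7304 CpGs) and in RPCs (34352 and 19253), and losses outnumber gains in aged cells (25548 and 3161).

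**Figure D4:**
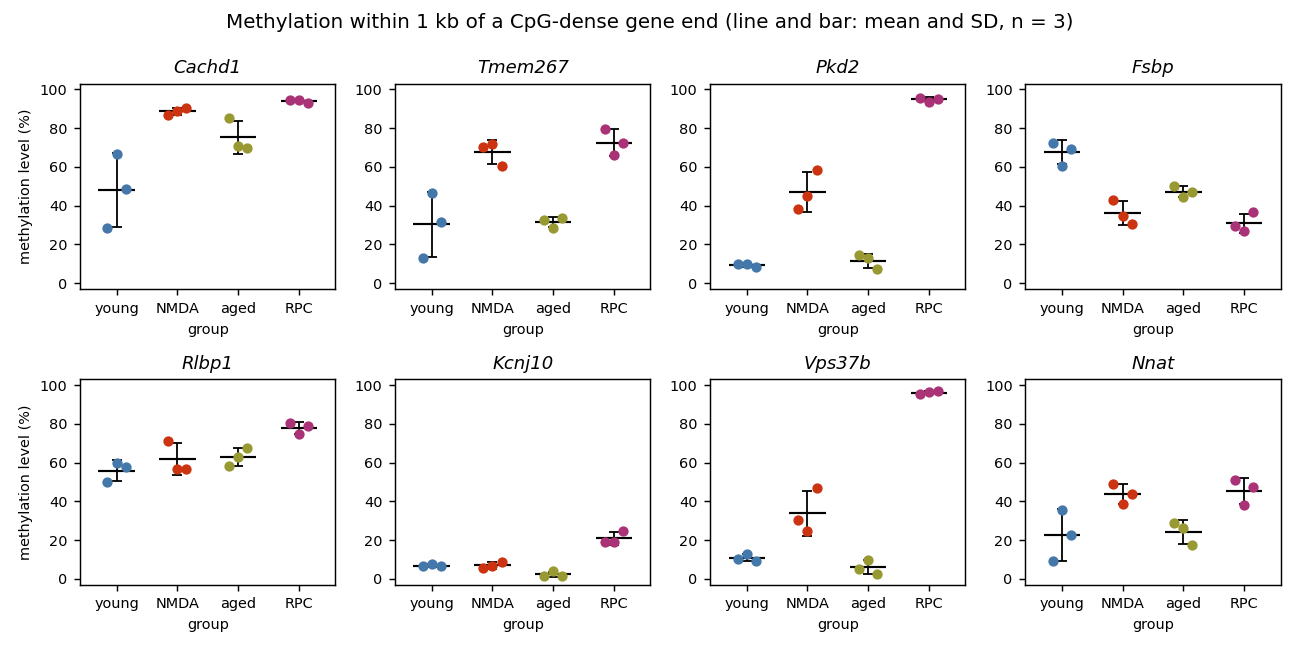
Methylation level in percent of 8 gene ends per RRBS library, each point 1 library, with mean and SD of each group of 3. Pkd2 rises from 9.29% in young cells to 47.3% after NMDA and 94.9% in RPCs, and Fsbp falls from 67.5% in young cells to 36.0% after NMDA.

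Gene ends and expression were then compared, in separate libraries of the 2 assays, first between RPCs and young cells. Over 8904 genes with both values, the Spearman rho of the differences was -0.024 (genes are not independent replicates). Of genes called in both, 33 had lower methylation and higher expression, 26 lower and lower, 61 higher and higher, and 64 higher methylation and lower expression (odds ratio 1.33, Fisher's exact p = 0.43, two-sided). Rlbp1 and Kcnj10 were among the last. The odds ratio was 1.68 without genes that contain another gene (exact p = 0.21) and 2.25 within 500 bp (exact p = 0.090). With at least 20 reads it was 2.39 (exact p = 0.028), and 3.31 without genes that contain another gene as well (exact p = 0.0070). The gene end was kept at 500 bp and 20 reads by a choice made after a first run, which moved the p at 20 reads from above to below 0.05. For NMDA and aged cells the rho was positive, 0.026 and 0.057. Over called gene ends alone it was -0.123 after NMDA, 0.197 in aged cells and -0.117 in RPCs. After NMDA 48 ends gained with higher expression and 20 with lower, and 5 lost with higher and 0 with lower (Fisher's exact p = 0.31). In aged cells these numbers were 6, 0, 7 and 1 (exact p = 1.0).

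Expression after NMDA was also set against the difference of RPCs from Müller cells, to ask whether injury moves cells toward the progenitor state. With no library shared, NMDA against young and RPC against aged cells gave a Spearman rho of 0.106 and a Pearson r of 0.017 across 18931 genes, with 1695 genes higher in both (1527 by chance), 1241 lower in both (784 by chance), 1880 higher after NMDA but lower in RPCs and 613 the reverse. The r turned negative without young replicate 2 (-0.011) and with a filter of 5 CPM (-0.0014). The rho was 0.0589 without young replicate 2 and 0.215 without genes that contain another gene. Without such genes 1109 were higher in both (866 by chance) and 906 lower in both (487 by chance). Higher after NMDA but lower in RPCs were then 752, and 347 the reverse. Genes high in NMDA and aged but low in young and RPC libraries, a pattern described below, would fall among the 1880 by construction. The other pair without a shared library, added later, NMDA against aged and RPC against young cells, gave rho 0.283 and r 0.266, with 1048 genes higher in both (714 by chance) and 1080 lower in both (462 by chance), 360 higher after NMDA but lower in RPCs and 393 the reverse. With the young libraries shared the r was 0.671, with 3585 genes higher in both (2080 by chance), 1599 lower in both (673 by chance), 645 higher after NMDA but lower in RPCs and 347 the reverse. Unchanged groups that share young libraries gave r 0.606 in simulation, against 0.495 observed on the same scale, with covariances of 0.236 and 2.72. Without shared libraries r on that scale was 0.0013 in simulation and -0.032 observed. For methylation with no library shared, 7457 CpGs were both higher after NMDA than in young cells and higher in RPCs than in aged cells (702 by chance), 286 were lower in both (127 by chance), 1240 went opposite ways, and r across CpGs was 0.353. These counts rest on NMDA calls of which 1 was left without young replicate 1. In the other pair, NMDA against aged and RPC against young cells, 3459 CpGs were higher in both (241 by chance), 35 lower in both (3.00 by chance), 112 went opposite ways, and r was 0.475. The chance counts treat positions, strands included, as independent. With reads pooled over CpGs, young and aged cells were both low (14.5 and 16.5%) and NMDA cells and RPCs both high (27.8 and 25.9%). An offset of this kind could give agreement without a shared library, which was not tested.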

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

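The fits without genes that contain another gene, the other gene end, the block with 2 groups alone and the kept gene end were chosen only after results were seen, and for every shift below the cause was not tested unless stated. Genes changed numbered 4895 for NMDA and 341 for aged cells with the 2 groups alone in the fit, and 3291 for aged cells with the Müller groups alone. Without genes that contain another gene they numbered 5176, 2605 and 7652 for NMDA, aged and RPC cells, partly because 12507 genes were then tested. Leaving out 1 library gave 3334 to 10469 for aged cells, lowest without aged replicate 1 or 2 and highest without young replicate 2.

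Replicate numbers gave no sign of pairing libraries. Residual correlations of libraries with equal numbers ran from -0.057 to 0.078 in RNA and from -0.035 to 0.042 in RRBS, with both signs and near 0. With 2 or 3 libraries per group such correlations cannot exclude pairing, so calls lost under the block are not set aside. With the block and 2 groups alone 543, 520 and 3021 genes changed in NMDA, aged and RPC cells. With the block 0 CpGs changed after NMDA with the quasi-binomial test (219268 at an unadjusted p under 0.05), while 22386 changed in aged cells and 41501 in RPCs.

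CpGs changed after NMDA numbered 1306 at 25 points and an adjusted p under 0.01, 39409 with no minimum difference, 94521 with a plain logistic model and 0 with the 2 groups alone (quasi-binomial test, 145710 at an unadjusted p under 0.05), and 4532 tiles changed. Leaving out 1 library gave 1 (young replicate 1) to 18660 (young replicate 3). For aged cells the numbers were 360, 111471, 77149, 0 (172540 at an unadjusted p under 0.05) and 751 tiles, and 10310 (aged replicate 1) to 31029 (young replicate 3). For RPCs they were 26676, 90777, 107790, 25319 and 8341 tiles. With no minimum aged cells thus had more CpGs called than RPCs. A stricter or absent minimum moves the count by construction. With no minimum the losses outnumbered the gains after NMDA (24052 and 15357) and in RPCs (54100 and 36677).

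Gene ends changed numbered 18, 7 and 106 for NMDA, aged and RPC cells at 25 points, 122, 39 and 212 within 500 bp, and 58, 18 and 123 at the other end, where 880 could be tested. Reads pooled over CpGs, which weight positions by coverage, put the mean level 13.3, 2.05 and 11.4 points above young cells, for aged cells with the sign turned. With each position weighted alike, the NMDA difference of 0.181 points ran from -0.156 to 0.583 with 1 library left out. Of 66 gene list tests 18 passed with camera, 0 with an estimated correlation and 35 with fry. The odds ratio of gene-end methylation and expression in RPCs was 2.39 with at least 20 reads (Fisher's exact p = 0.028), and 3.31 without genes that contain another gene as well (exact p = 0.0070). For the first of these the p moved from above to below 0.05 when the gene end was kept fixed, a choice made after a first run. The rho of injury and developmental directions was 0.215 without genes that contain another gene, and 0.0589 (without young replicate 2) to 0.116 (without NMDA replicate 3) with 1 library left out, while r turned from 0.017 to -0.011 without young replicate 2. In the added pair of NMDA against aged with RPC against young cells it was 0.283, and 0.197 (without young replicate 2) to 0.287 (without NMDA replicate 3) with 1 library left out.

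Signs reversed at a few gene ends. In aged cells Bnipl was at 4.30 points, Osgin1 at -4.84, Thoc1 at -3.42 and Dazl at -1.60 within 500 bp, and Dazl was at -0.451 and Pdgfrb at -2.14 with at least 20 reads. In RPCs Dazl was at -0.195 with at least 20 reads and -1.30 within 500 bp. The expression of Bfsp2 in RPCs, not called, was at log2 6.49 without young replicate 1 and -3.74 without young replicate 2. Of named genes called, 30 of 71 after NMDA, 20 of 67 in aged cells and 64 of 79 in RPCs were called under every alternative, and of named gene ends 18 of 24, 14 of 21 and 21 of 25.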

Other observations

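NMDA cells were also compared with aged cells, a comparison chosen only after results were seen, as were the tests below on genes that contain another gene, gene length, coverage and imprinted ends. Gfap was higher after NMDA by log2 4.01 ± 0.43 (978 ± 167 against 57.3 ± 17.4 CPM, n = 3 and 2, edgeR adjusted p = 5.8e-04), Vim, another filament gene, by 2.05 ± 0.19 and Osmr by 1.49 ± 0.14. Glul was lower (log2 -2.81 ± 0.26), as were Rlbp1 (log2 -1.53 ± 0.36), Insig1 (log2 -1.69 ± 0.22), Nrarp (log2 -4.38 ± 0.38) and Hes5 (log2 -2.95 ± 0.33). Of 26 gliosis genes 14 rose, 17 when adjusted over the list alone (camera adjusted p = 3.4e-09; adjusted p = 0.20 with an estimated correlation). Of 16 cholesterol synthesis genes 11 fell, also adjusted over the list alone (camera adjusted p = 3.0e-05; adjusted p = 0.25 with an estimated correlation). Of 20 proliferation genes 12 rose, 13 when adjusted over the list alone (camera adjusted p = 3.0e-05; adjusted p = 0.40 with an estimated correlation), with Cdk1 at log2 3.35 ± 0.43. Of 17 DNA methylation genes 4 rose and 2 fell, 4 and 4 when adjusted over the list alone (camera adjusted p = 0.71), with Uhrf1 at log2 3.66 ± 0.23. Markers of other cells rose too, for 6 of 16 microglia genes, 10 when adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.77 with an estimated correlation), and for 2 of 20 photoreceptor genes, 1 when adjusted over the list alone (camera adjusted p = 0.0012; adjusted p = 0.74 with an estimated correlation). Some lists with rises against young cells had few or none against aged cells. Vascular genes had 1 up and 2 down of 11, inner retinal neuron genes 2 and 2 of 20, and pluripotency genes 1 and 1 of 7. None of 8 pigment cell and 4 germline genes passed with edgeR. Other lists kept part of their rise: 7 of 22 interferon, 5 of 15 senescence and 4 of 24 neurogenic genes were higher and 0 lower. In all 3844 genes differed, 1988 higher and 1856 lower, and 1516 were higher and 1210 lower than in both young and aged cells. At gene ends 107 gained and 4 lost methylation, with Parp16 at 57.2 ± 9.98% against 15.2 ± 3.78% (SD, n = 3 each) and Pkd2 at 47.3 ± 10.4% against 11.4 ± 3.78%. Without genes that contain another gene 2761 genes differed, 1337 higher and 1424 lower, so the balance turned. No other alternative was run for the calls of this comparison.

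In RNA, 195 genes, Lhx2, Trpm3, Gnas and Rnf213 among them, had at least 10 CPM in every NMDA and aged library and at least 8 times the level of any young or RPC library, though some stayed well expressed there (Son at 50.1 CPM in young cells and 29.2 in RPCs), whereas other splits of the groups gave 0 to 12. Counting that drops reads of genes containing another annotated gene in the young and RPC libraries could produce this. Of the 187 genes matched to the reference 87.7% contained another gene, against 27.4% of 9914 expressed genes, and the odds ratio within bins of gene length was 9.55 (95% interval 5.90 to 15.5), which fits this explanation. A bias against long genes could also play a part, and 1.39% (0.668 to 2.54%, exact binomial) of the longest genes without another gene showed the pattern, which leaves it open. Changes of the aged and injured cells may add to it, and neither test excludes them.

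In RRBS, young libraries had more CpGs at low intermediate levels, and losses against young cells at CpGs of low level may come from this. At 250289 positions chosen to be near 0 in NMDA and RPC libraries, the mean level was 2.50, 2.48 and 1.70% in young and 0.188 to 0.227% in aged libraries. At 322512 positions chosen in aged and NMDA libraries it was 2.63, 2.60 and 1.80% in young and 0.402, 1.18 and 0.829% in RPC libraries, a smaller gap. Incomplete bisulfite conversion shared by nuclear and mitochondrial DNA could raise it. Mitochondrial levels were 29.4, 26.8 and 4.75% in young libraries. They were 0.181 to 0.263% in aged, 0.292 to 0.774% in NMDA and 1.67 to 7.30% in RPC libraries. Every young library thus lay above every aged and NMDA library, and nuclear levels of the young libraries fell in the same order. The nuclear level of young replicate 3 was, however, 0.681 of that of replicate 1, which argues against conversion failing in proportion in both. Shared failure out of proportion and failure in nuclear DNA alone stay open. Lower coverage could also raise the young level, but the lowest median coverage of a young library was 104 reads against 86 to 100 in aged libraries, which argues against it.

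NMDA libraries lay closer to RPCs than young or aged ones at CpGs that separate aged cells from RPCs. At 3941 CpGs low in aged cells the RPC-like share was 0.230, 0.225 and 0.382 after NMDA and 0.0433, 0.0502 and 0.0330 in young libraries, and at 164 CpGs high in aged cells it was 0.0899, 0.137 and 0.146 after NMDA and 0.0465, 0.0288 and 0.0602 in young libraries, a narrower gap. Admixed cells with an RPC-like methylome could give this. The ratio of the 2 shares was 0.461 ± 0.129 (SD, n = 3; 0.390, 0.610 and 0.382), on both sides of the limit of 0.5 set beforehand, which leaves it open. This test covers RPC-like cells only. Methylomes of other cells, such as the microglia whose markers rose in RNA after NMDA, were not measured, so their admixture was not tested. Incomplete conversion of young libraries could not explain a share of at least 0.225 measured against aged cells. Loss of methylated molecules in young libraries may lower imprinted ends (10.4, 37.7 and 28.1% in young and 47.8, 38.6 and 41.5% in NMDA libraries, 6 ends of which 2 share a window), and young replicate 2 had a share of 0.0502 against a limit of 0.113 derived from the lowest NMDA share, which stays open because 1 library decides nothing. Aged libraries were low at these ends too (26.1, 28.9 and 18.7%), and RPC libraries stood at 49.9, 39.1 and 43.5%. The RPC-like share is measured against aged cells. Whether a loss shared by young and aged libraries raised it was not tested.

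The 6 RRBS libraries of each comparison can be split in 10 ways, too few for a test at 5%. In each of the 6 comparisons of CpGs or gene ends, 1 of 10 splits, the real one, gave as many calls. For CpGs after NMDA the real split gave 21593 and the highest other 14, for aged cells 28709 and 0, for RPCs 53605 and 0. For gene ends the real splits gave 205, 75 and 385, and the highest other gave 0 in each.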
